A study of Rattus norvegicus with 4 samples.

How the data were processed

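Liver RNA of 4-month-old male WNIN/Ob rats was measured on Affymetrix Rat Gene ST arrays. WNIN/Ob is a rat strain of Wistar origin kept in Hyderabad in which obese animals occur beside lean ones. Per the labels' protocols, RNA of 4 lean animals was combined into a lean pool and RNA of 4 obese animals into an obese pool, and 100 ng of each pool was amplified and labelled. Each pool was hybridised to 2 arrays, which the labels call original and technical replicate. Arrays were assigned to the lean or obese group from the phenotype in the labels, and all 4 arrays were used.

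The deposited values are intensities on a linear scale, 1 per probe set and array, that the authors computed with RMA, per the submitters' processing notes. RMA corrects the background, normalises between arrays and summarises the probes of a probe set. It usually returns log2 values, so the step that brought the values to a linear scale, like the software version and the genome build, is not given in the sources used here. The linear scale was read from the values, which ran from 2.31 to 14288 with medians between 25.73 and 27.69. The log2 of each value was taken here before any mean or difference, and no further normalisation was applied in the values reported. The medians of the arrays on the log2 scale were 4.77 and 4.75 for the lean pool and 4.69 and 4.79 for the obese pool. RMA pulls in the values of very dim and very bright probe sets, so folds at either end of the scale understate differences. Scanner files and detection calls were not used here, so another background correction at the probe level was not tried and no gene is known to lie above background. A fold against a pool whose level lies below the level filter therefore has no firm size.

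Of 29214 probe sets, 15310 carried 1 gene symbol in the platform annotation, 323 carried several and 13581 were not listed there. No gene was named from a probe set with several symbols. The gene table of assembly GRCr8 held the gene identifier of 15279 of the 15310 and changed 0 symbols; because the build used by the authors is not known, it served for names only and no coordinates are given. Where a gene had several probe sets, as 526 genes did, the probe set with the highest mean over the 4 arrays was taken, which left 14507 genes. Among the genes past the 2-fold rule described next, 10 had more than 1 probe set, and 0 of these had a probe set of the opposite sign.

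A pool's level is the mean of its 2 arrays on the log2 scale, and the difference is obese minus lean. Because each phenotype is represented by 1 pool, the arrays are technical replicates, no test across animals exists and no p-values were computed. A gene was counted as 2-fold higher or lower in the obese pool when the difference reached a factor of 2, the nearest arrays of the pools lay at least 0.5 apart on the log2 scale, and the higher pool's level reached the median of all genes (5.48). A smaller rule, used for members of gene lists, asked for a factor of 1.5 and a gap of 0.25. A fold is given with its range over the 4 pairs of a lean and an obese array. This range covers measurement error only and leaves out differences between animals, and the number of arrays limits its precision.

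The gene lists covered lipogenesis and triglyceride synthesis, cholesterol synthesis and uptake, fatty acid oxidation and ketogenesis, fatty acid uptake and lipid droplets, bile acids, lipoproteins, gluconeogenesis and insulin-repressed genes, and glucose use and glycogen. Further lists covered glucocorticoids, retinoids, xenobiotic metabolism, male-biased and female-biased liver genes, the leptin, adiponectin and growth hormone axis, the acute phase, stress of the endoplasmic reticulum, oxidative stress, oxidative phosphorylation, the urea cycle and amino acid breakdown, the circadian clock and the cell cycle. Cell type lists held markers of macrophages, lymphocytes, stellate cells and fibrosis, endothelium, bile duct, hepatocytes, adipocytes, blood cells and pancreas. For each of these 30 lists the median difference of the measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean level so that levels matched. That percentile describes these arrays only.

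These 30 lists, the size rules, the rule for named genes and the alternatives listed in the last paragraph, except where marked there, were fixed before the data were examined. Genes named are the 12 largest differences in each direction past the 2-fold rule, without placeholder symbols, up to 4 members of each list past the 1.5-fold rule, and Alb and Apoa1 as abundant liver transcripts. Lepr and Leprot were also to be named, but they share a probe set that carries both symbols and are not reported here. A textbook list of skeletal muscle genes in 6 classes, with short lists of heart-restricted and smooth muscle genes, was written only after the 60 largest decreases had been seen. Genes named outside the rule, which are Lpin1, Pck1, Igf1, Bub1b, Ctrb1, some marker genes of the stellate list, Fasn in a figure and further genes under the other observations, were chosen after their values were seen, except Cish.

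Both rules were tested on simulated data with known differences in 14507 genes for the comparison of the obese with the lean pool. The 2-fold rule called 50 of 50 genes at simulated folds of 2.5, 4 and 8, 0 of 50 at a fold of 1.5 and 0 of 14307 unchanged genes. The 1.5-fold rule called 23 of 50 genes at a fold of 1.5, 50 of 50 at each larger fold and 6 of 14307 unchanged genes. Noise between arrays was simulated, whereas differences between animals were not. The changed genes were drawn only from genes whose mean reached the median level, so the level filter was not tried on them. The calls therefore do not show how the rules recover changes in dimmer genes.

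The alternatives tried were centring each array on its median, cyclic loess between the arrays, an offset of 16 on the linear scale, no filter on the level or a filter at the 75th percentile, no minimum gap between arrays, and the mean of a gene's probe sets. All probe sets were also counted, named or not, and results were computed from the original arrays alone, from the technical replicate arrays alone, and without each array in turn. Results without the skeletal muscle genes were added after the data had been seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess.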

Results

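Gene expression in the liver of 4-month-old male WNIN/Ob rats was measured on 4 arrays, 2 of a pool of RNA from 4 lean animals and 2 of a pool from 4 obese animals. The series asks how baseline liver expression differs between the lean and the obese phenotype of this strain. Of the 14507 genes measured, 4 were 2-fold apart between the lean arrays and 13 between the obese arrays, against 348 to 399 between single arrays of the different pools. The standard deviation of the difference between arrays over genes was 0.20 on the log2 scale in the lean pool and 0.27 in the obese pool, and 0.48 to 0.52 between pools. Each phenotype was measured as 1 pool, so every value below compares these pools and has no replicate check across animals.

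The obese pool carried more transcript of genes that make fatty acids and triglycerides, and the lean pool carried abundant transcripts of skeletal muscle. Pnpla3, which encodes a lipid droplet acylhydrolase, was 15.3-fold higher in the obese pool (13.7 to 17.0 over the 4 pairs of arrays), and Elovl6, an elongase of long-chain fatty acids, 14.4-fold (11.9 to 17.5). Acta1, the actin of skeletal muscle, was 74.5-fold lower in the obese pool (73.0 to 76.1). Of the abundant liver transcripts, albumin (Alb) differed by a fold of 1.05 (0.999 to 1.11) and stood at 13.67 ± 0.07 in the lean and 13.74 ± 0.03 in the obese pool (log2 intensity, SD of 2 arrays). Apoa1, the main protein of high-density lipoprotein, was 1.33-fold higher in the obese pool (1.3 to 1.36), at 12.21 ± 0.00 and 12.62 ± 0.04.

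By the 2-fold rule 83 genes were higher and 215 lower in the obese pool. By the 1.5-fold rule 317 were higher and 352 lower, a split that cyclic loess between the arrays moved to 227 higher and 400 lower. The count of 1.5-fold higher genes also hung on which obese array was used. It was 553 without the obese technical replicate array and 258 without the obese original array. The upper quartile of log2 intensity was 6.62 on the obese original array and 6.5 to 6.52 on the other arrays. Of the 215 lower genes, 99 stood on the list of skeletal muscle genes and 116 did not.

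**Figure D1:**
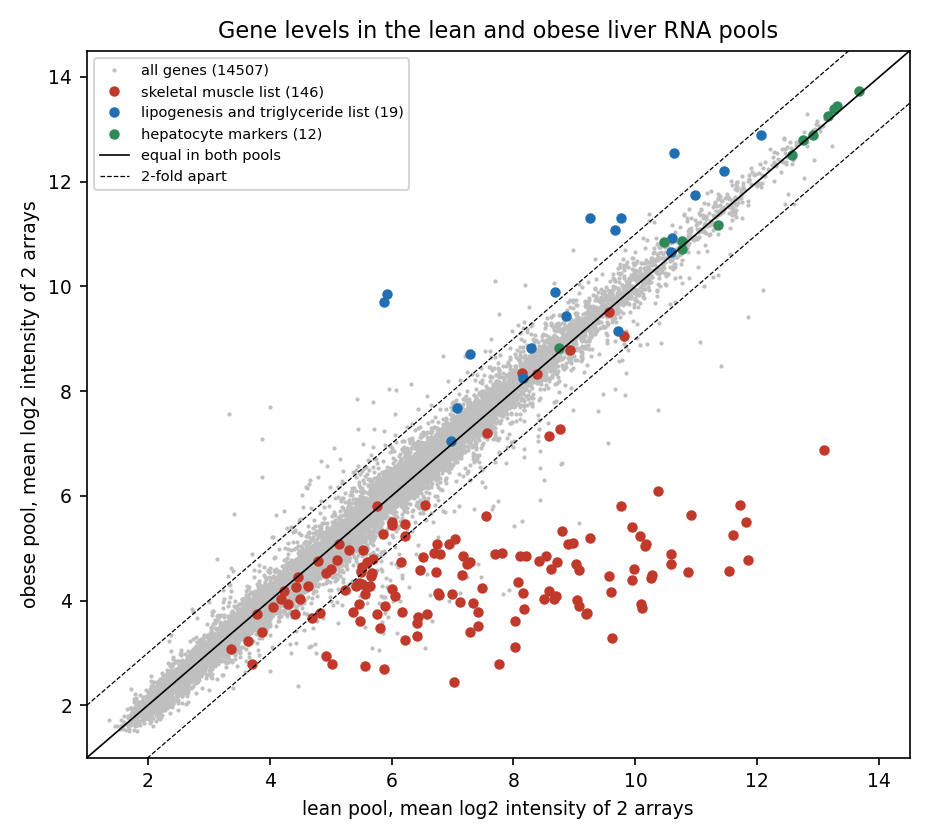
Mean log2 intensity of each of 14507 genes in the lean pool (x axis) and the obese pool (y axis), 2 arrays per pool, with the dashed lines 2-fold from equality. By the 2-fold rule 99 of the 146 skeletal muscle genes (red) are lower and 8 of the 19 lipogenic genes (blue) higher in the obese pool, and the 12 hepatocyte markers (green) lie near equality.

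The 12 genes with the largest excess in the obese pool held Pnpla3, Elovl6 and genes of varied function. Sdr16c6, a short-chain dehydrogenase of the retinol dehydrogenase group, was 18.9-fold higher (15.6 to 22.8) from a lean level of 3.33. Akr1b7, an aldo-keto reductase, was 12.8-fold higher (9.53 to 17.3) and Anxa8, a calcium-dependent phospholipid-binding annexin, 9.26-fold (6.93 to 12.4). The remaining genes among the 12 were Hspa4l (5.62-fold), a chaperone of the heat shock family, Prss32 (5.33-fold), a serine protease, Cyp7a1 (5.28-fold), Fabp2 (4.73-fold), Cyp17a1 (4.29-fold), a hydroxylase of androgen synthesis, Enpp5 (4.22-fold) and Gpam (4.12-fold). For 6 of the 12, which were Sdr16c6, Akr1b7, Anxa8, Hspa4l, Prss32 and Fabp2, the lean level lay below the level filter and is not shown to be above background, so their folds give no firm size or order.

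Genes of muscle contraction and muscle energy supply made up all 12 of the largest decreases. They included Myl1, a myosin light chain of fast fibres, 134-fold lower in the obese pool (126 to 143), the fast myosin heavy chains Myh1, 126-fold (88.2 to 180), and Myh2 (76.2-fold), the fast troponin Tnnt3 (81.9-fold), the Z-disc protein Myot (80.2-fold) and the calcium pump Atp2a1 (79.1-fold). Acta1 stood at 13.10 ± 0.02 in the lean pool and at 6.88 ± 0.02 in the obese pool. Muscle glycogen phosphorylase (Pygm) was 79.8-fold, creatine kinase (Ckm) 59.5-fold and myoglobin (Mb) 59.0-fold lower, and the slow fibre genes Mybpc1 and Myh7 were 71.4-fold and 56.3-fold lower. For 9 of these 12 genes, all but Acta1, Atp2a1 and Ckm, the obese level lay below the level filter and is not shown to be above background, so their folds give no firm size or order. Of 146 measured genes on the skeletal muscle list, 99 were 2-fold lower in the obese pool and 0 higher, with a median difference of -2.45. The 20 largest decreases were all on that list, as were 48 of the 50 largest and 73 of the 100 largest. The list was written after the largest decreases had been seen, so its count is not independent evidence of its direction.

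**Figure D2:**
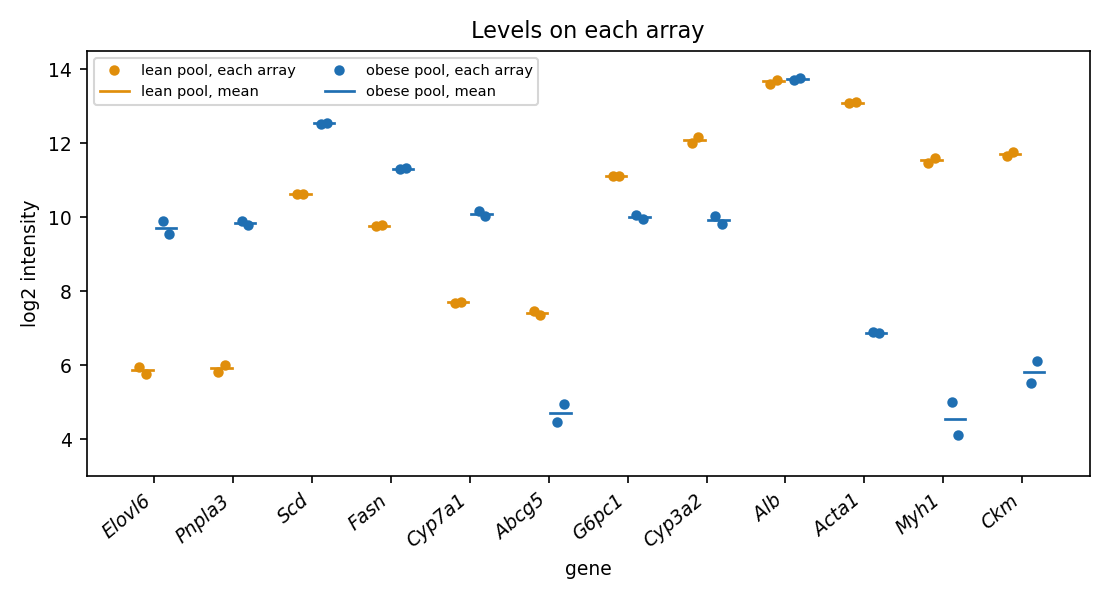
Log2 intensity of 12 genes on each of the 2 arrays of the lean pool (orange) and of the obese pool (blue), with lines at the pool means. The arrays of a pool lie close together for Scd, Fasn, Cyp7a1 and Acta1, farther apart for Myh1 and Ckm in the obese pool, and Alb is near 13.7 on all 4 arrays.

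Lipogenic genes were higher in the obese pool as a group. Of 19 measured members of the list of lipogenesis and triglyceride synthesis, 12 were at least 1.5-fold higher and 0 lower, and the median difference of 0.76 lay at percentile 100.0 of random lists of matched level. Gpam, the acyltransferase that starts glycerolipid synthesis, was 4.12-fold higher (3.98 to 4.26), and Scd, the desaturase that makes oleate, 3.76-fold (3.73 to 3.79). Lpin1, named after its value was seen, had a difference of -0.56 and was the only member of the list below 0. Cholesterol genes shared the direction at smaller size: 9 of 19 were 1.5-fold higher and 0 lower, with a median of 0.52 at percentile 100.0. The largest of these was Dhcr7, which catalyses the last step of cholesterol synthesis, at 1.83-fold (1.73 to 1.93). Sqle, the squalene epoxidase, was 1.71-fold higher (1.53 to 1.91), Fdps, which makes farnesyl diphosphate, 1.67-fold (1.64 to 1.69) and Pmvk, a kinase of the mevalonate pathway, 1.66-fold (1.60 to 1.72).

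Fatty acid oxidation genes were also mostly higher, with a median of 0.30 at percentile 100.0, and 19 of 24 genes lay above 0, although only 4 were 1.5-fold higher and 2 were lower. Cyp4a1, a fatty acid hydroxylase, was 2.27-fold higher (2.14 to 2.41), Vnn1, a pantetheinase, 2.13-fold (1.83 to 2.49) and the hepatokine Fgf21 1.84-fold (1.64 to 2.08). Pdk4, a kinase that restrains pyruvate oxidation and is also on the muscle list, was 1.68-fold lower (1.55 to 1.82). Among 21 genes of fatty acid uptake and lipid droplets 5 were higher and 4 lower, with a median of 0.17 at percentile 97.1. Fabp2, a fatty acid-binding protein best known from the intestine, was 4.73-fold higher (3.95 to 5.67). Fitm1, lipoprotein lipase (Lpl) and the very-low-density lipoprotein receptor (Vldlr) were 13.2-fold (11.9 to 14.7), 5.72-fold (4.94 to 6.63) and 2.99-fold (2.69 to 3.34) lower. Muscle, whose own transcripts were abundant in the lean pool, also expresses these genes. The obese levels of Fitm1 and Vldlr and the lean level of Fabp2 lay below the level filter, so their folds have no firm size.

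Genes of bile acid and sterol handling went both ways. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 5.28-fold higher in the obese pool (5.0 to 5.58), whereas Abcg5 and Abcg8, which together form the canalicular sterol exporter, were 6.56-fold (5.34 to 8.06) and 4.80-fold (3.33 to 6.92) lower. Both exporter genes lay below the level filter in the obese pool, at 4.71 and 3.69, so their folds have no firm size. Slco1a4, a transporter for organic anions, was 2.43-fold lower (2.22 to 2.66). Over the list of 20 genes 1 was 1.5-fold higher and 5 lower, and the median was -0.06, at percentile 1.0. That place rested on the array run, as the median was 0.00 on the original arrays alone and -0.02 without the obese technical replicate array. Lipoprotein genes had a median of 0.07, at percentile 47.6, with 3 of 20 higher and 0 lower. Those 3 were Angptl8, an inhibitor of lipoprotein lipase activity, at 2.55-fold (2.27 to 2.87), Apoa4 at 1.72-fold (1.64 to 1.81) and Mttp, which loads lipid onto apolipoprotein B, at 1.51-fold (1.46 to 1.58).

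In glucose metabolism 2 genes of glucose use were higher and 5 genes of glucose output and insulin repression lower in the obese pool. Pklr, the liver pyruvate kinase, was 2.24-fold higher (2.20 to 2.28) and Ppp1r3b, which targets a phosphatase to glycogen, 1.94-fold (1.75 to 2.14). They were the 2 of 12 genes of glucose use and glycogen past the 1.5-fold rule, and the list's median of 0.33 lay at percentile 99.8. G6pc1, the catalytic subunit of glucose-6-phosphatase, was 2.17-fold lower (2.08 to 2.27) and Igfbp1, a secreted protein repressed by insulin, 2.28-fold (2.01 to 2.58). Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes, was 2.60-fold lower (1.99 to 3.40) and the aminotransferase Got1 1.91-fold (1.85 to 1.97), both of them genes that muscle expresses as well. Ppargc1a lay below the level filter in the obese pool, so its fold has no firm size. Of the 14 genes of gluconeogenesis and insulin repression 5 were lower and 0 higher, and the median was -0.03, at percentile 5.8. That median took either sign, at -0.12 without the obese original array and 0.02 without the obese technical replicate array. The rate-limiting enzyme Pck1, named after its value was seen, had a difference of -0.26.

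Genes with higher expression in male than in female rat liver were lower in the obese pool. All 9 measured members had differences below 0, 6 were 1.5-fold lower, and the median of -1.03 lay at percentile 0.0. The steroid-hydroxylating cytochromes Cyp3a18 and Cyp3a2 were 7.55-fold (6.49 to 8.79) and 4.46-fold (3.91 to 5.08) lower, the transporter gene Ust5r 2.04-fold (1.64 to 2.54) and carbonic anhydrase Car3, which muscle also expresses, 2.05-fold (1.75 to 2.40). Of 5 female-biased genes, the prolactin receptor Prlr was 3.52-fold higher (3.05 to 4.06) and the oxidase Hao2 2.15-fold lower (2.00 to 2.31), with a median of 0.23 at percentile 90.5 that was 0.11 without the obese original array and 0.37 without the obese technical replicate array. Prlr lay below the level filter in the lean pool, so its fold has no firm size. Socs2, a feedback inhibitor induced by growth hormone, was 4.56-fold lower (3.96 to 5.26) and the only gene of 16 in the leptin, adiponectin and growth hormone list past the rule. That list's median was -0.02, at percentile 6.2, and Igf1, named after its value was seen, had a difference of -0.03.

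Xenobiotic metabolism held 1 higher and 3 lower genes of 19, with a median of -0.13 at percentile 0.0. Besides Cyp3a18, which is on this list too, the monooxygenase Fmo1 was 2.83-fold lower (2.53 to 3.16) and the nuclear receptor Nr1i3, which senses foreign compounds, 2.07-fold (1.91 to 2.24). Its inducible target Cyp2b2 was 3.63-fold higher (3.32 to 3.97), from a lean level below the level filter, so its fold has no firm size. Without the obese technical replicate array the median of this list was -0.03. Retinoid genes had a median of 0.06, at percentile 49.8, with 4 of 18 higher and 1 lower. Rdh16, a retinol dehydrogenase, was 2.13-fold lower (2.02 to 2.25), Aldh1a1, which makes retinoic acid, 1.82-fold higher (1.63 to 2.03), Adh7 1.77-fold (1.63 to 1.92) and Bco1, which cleaves carotene to retinal, 1.57-fold (1.39 to 1.78). None of the 9 genes of glucocorticoid metabolism and response passed the 1.5-fold rule, and their median was -0.06, at percentile 5.0.

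**Figure D3:**
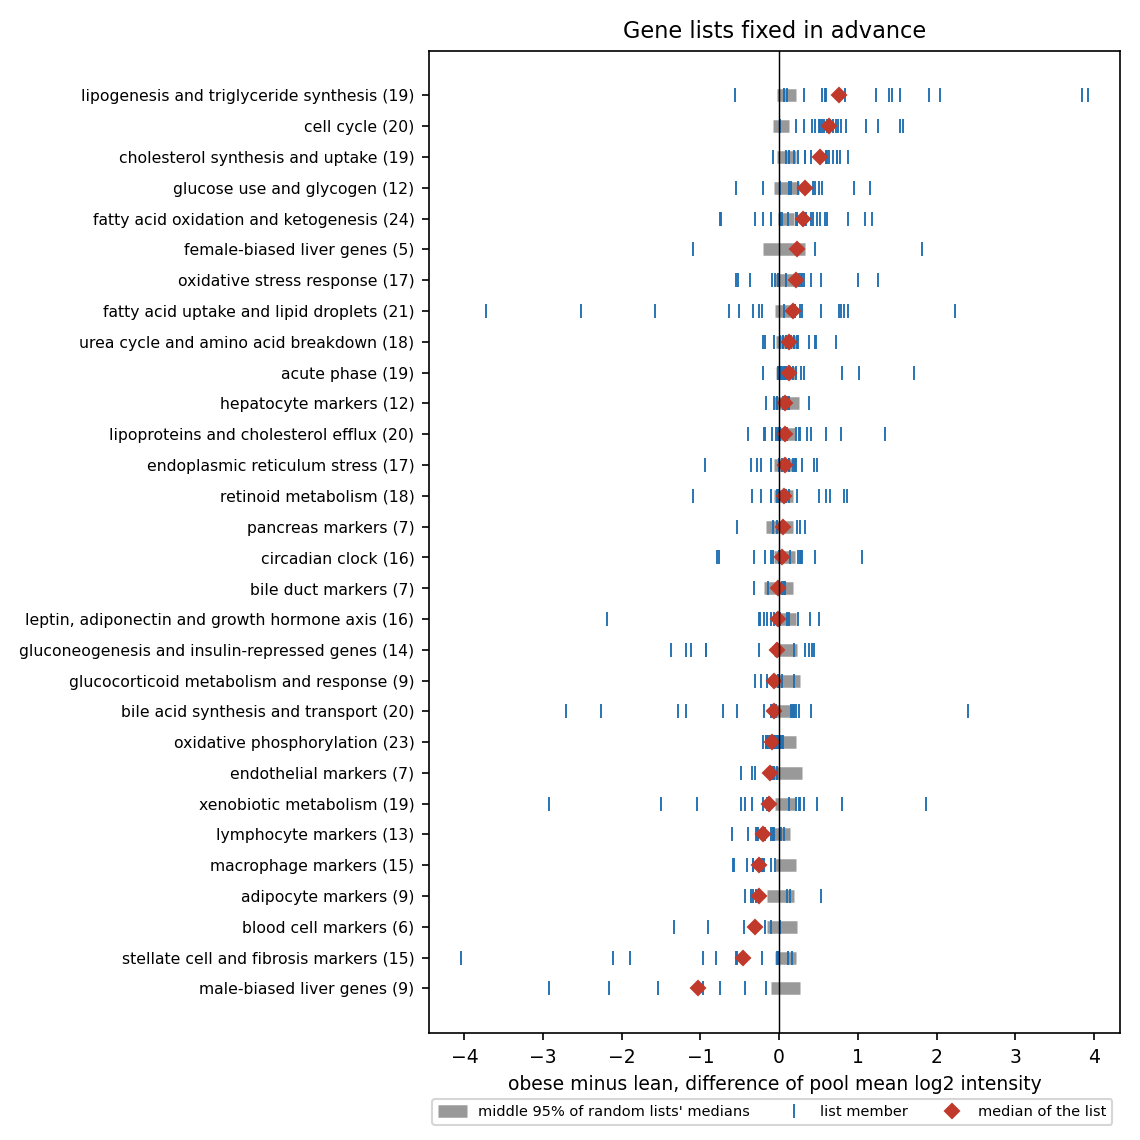
Obese minus lean difference of log2 intensity for the members (blue ticks) and the median (red diamond) of 30 gene lists, with the number of measured members in brackets. Grey bars span the middle 95% of the medians of 10000 random lists of matched level; lipogenesis (0.76) and the cell cycle (0.63) have the highest medians and the male-biased genes (-1.03) the lowest.

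Acute phase genes stood out singly and not as a list. Hamp, the iron-regulating hormone hepcidin, was 3.29-fold higher (3.24 to 3.34), the plasma glycoprotein Orm1 2.03-fold (1.85 to 2.23) and the protease inhibitor A2m 1.74-fold (1.57 to 1.94), while the other 16 genes passed no rule and the median was 0.12, at percentile 72.6. Hmox1, which degrades haem, was 2.40-fold higher (2.25 to 2.56) and the quinone reductase Nqo1 2.00-fold (1.77 to 2.27). The 17 genes of oxidative stress had a median of 0.22 at percentile 97.9, which was between 0.11 and 0.19 when an array was left out. Of 17 genes of stress of the endoplasmic reticulum only Xbp1, a transcription factor of the unfolded protein response, passed the rule, at 1.91-fold lower (1.88 to 1.94), and the median was 0.07, at percentile 45.7.

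Transcripts of oxidative phosphorylation were slightly lower, with a median of -0.09 at percentile 0.1, and 0 of 23 genes passed the 1.5-fold rule. The median was -0.05 without the obese technical replicate array and -0.18 with cyclic loess. Urea cycle and amino acid genes had a median of 0.13 (percentile 76.2), and of 18 only Gldc, of the glycine cleavage system, passed the rule, at 1.65-fold higher (1.53 to 1.78). Clock genes had a median of 0.04 (percentile 36.6), with Per2, a repressor in the clock loop, 2.07-fold higher (1.93 to 2.22) and Nr1d1, a repressor of Bmal1, 1.73-fold lower (1.63 to 1.84). Per2 lay below the level filter in the lean pool, so its fold has no firm size. The time of day at which each animal was sampled is not given in the labels.

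Cell cycle genes were higher in the obese pool as a group, with a median of 0.63 at percentile 100.0, and 5 of 20 measured members passed the 1.5-fold rule. All 20 had differences above 0, down to 0.01 for Bub1b, whose array pairs ran from -0.21 to 0.24. Rrm2, a subunit of ribonucleotide reductase, was 3.0-fold higher (2.32 to 3.87), the topoisomerase Top2a 2.91-fold (2.07 to 4.09), the thymidylate synthase Tyms 1.73-fold (1.44 to 2.07) and the cyclin Ccnd1 1.65-fold (1.40 to 1.94). The transcripts were dim, with a median level of 4.26 in the lean and 4.87 in the obese pool, and 6 of the 20 reached the level filter of 5.48 in the obese pool. An offset of 16 on the linear scale, which shrinks differences of dim genes, brought the median to 0.36.

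Among markers of other liver cell types, 4 genes of the stellate cell and fibrosis list and 2 of the blood cell list were lower in the obese pool, and no marker was higher by the 1.5-fold rule. The macrophage markers had a median of -0.25 (percentile 0.0) and the lymphocyte markers one of -0.21 (percentile 0.1), with 0 of 15 and 0 of 13 past the 1.5-fold rule. Endothelial markers had a median of -0.12 (percentile 2.0) and adipocyte markers one of -0.26 (percentile 0.3), and none of the 7 and 9 genes passed. Without the obese technical replicate array the medians were -0.16 for macrophages and -0.04 for endothelium, and without the obese original array -0.24 for endothelium and -0.14 for adipocytes. The adipocyte median changed sign to 0.10 over the members that reached the level filter and was -0.04 on the technical replicate arrays alone, and the lymphocyte median was -0.09 with an offset of 16. Of 15 stellate cell and fibrosis markers 4 were lower, among them desmin (Des), 16.6-fold (13.7 to 20.1), which is also on the muscle list. Desmin lay below the level filter in the obese pool, so its fold has no firm size. The matrix genes Dcn, Col1a1 and Lox were 3.73-fold (3.0 to 4.64), 1.96-fold (1.82 to 2.11) and 1.74-fold (1.47 to 2.07) lower. That list's median was -0.46 (percentile 0.0), or -0.34 without desmin. Of its 15 differences 12 were below 0 and 3 above, and some members differed little, such as Reln (-0.03), Pdgfrb (0.11) and Timp1 (0.16). Whether the lower genes reflect stellate cells or other tissue in the lean pool was not tested. Of 6 blood cell markers, Alas2 of red cell haem synthesis was 2.53-fold lower (2.35 to 2.72) and beta-globin (Hbb) 1.86-fold (1.80 to 1.92), with a median of -0.31 (percentile 0.2). The medians of bile duct markers (-0.01, percentile 43.4), pancreas markers (0.05, percentile 65.3) and hepatocyte markers (0.08, percentile 48.0) lay inside the range of random lists. The medians of the clock, glucocorticoid, bile duct and pancreas lists took either sign when an array was left out. Across the 30 lists 6 medians lay above and 10 below the middle 95% of random lists, where 1.5 would lie outside if genes varied independently. Genes of a list can vary together and some lists share members, so the excess over 1.5 is no measure against chance. The abundant muscle transcripts of the lean pool accompany all of these differences.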

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

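Probe sets that carry no gene symbol or several, which no gene comparison used, also differed between the pools. Of 13904 such probe sets, 23 were at least 2-fold higher and 82 at least 2-fold lower in the obese pool by the same rule. The largest increases were in probe sets 10915578 (2.81 on the log2 scale) and 10936048 (2.52), and the largest decreases in 10769959 (-6.10) and 10846346 (-5.20). These probe sets were looked at because they lie outside the genes the report describes, and their genes are not named here.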

How the results depend on the processing

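Among counts of genes, 50 of 60 alternative values stayed within 1.5 times the reported count, and 0 of the 105 named genes past a rule changed sign. The minimum gap between the arrays of the pools largely fixed that sign beforehand in the runs on fewer arrays. Of 1070 alternative differences of named genes, 271 moved by more than the gene's technical spread. Every list with a median outside the middle 95% of random lists kept its sign in every alternative run, except the adipocyte markers, while the bile acid median reached 0.00. A kept sign does not place a median outside that range, which was not computed again. Over the array pairs the oxidative stress median ran from 0.11 to 0.16, inside the main range of -0.05 to 0.21. The highest pair also lay inside for endothelium (-0.04, lower bound -0.11), xenobiotics (-0.03, lower bound -0.05) and adipocytes (-0.04, lower bound -0.16). Of 332 alternative list medians 259 moved by less than the technical spread. The cause of the shifts was not tested, except where a setting adds or removes genes, members or arrays. Counting all probe sets gave 506 and 607 probe sets 1.5-fold higher and lower and 337 2-fold lower. The filter at the 75th percentile left 194 and 188 genes at 1.5-fold and 50 and 126 at 2-fold, higher and lower. Leaving out the skeletal muscle genes, an alternative added after seeing the data, left 116 genes 2-fold lower, and the stellate list without desmin had a median of -0.34. The original arrays alone gave 616 genes 1.5-fold higher, and leaving out an array 258 to 553.

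With cyclic loess, list medians were 0.06 for the acute phase, -0.14 for bile acids, -0.02 for the clock, -0.01 for endoplasmic reticulum stress, 0.24 for fatty acid oxidation, -0.11 for gluconeogenesis and 0.26 for glucose use. They were 0.01 for hepatocyte markers and lipoproteins, -0.10 for the leptin list, -0.18 for oxidative phosphorylation, 0.13 for oxidative stress and 0.05 for the urea cycle. Centring gave -0.01 for gluconeogenesis and 0.35 for glucose use. An offset of 16 gave 0.36 for the cell cycle and 0.13 for oxidative stress. Restricted to members at the level filter, medians were 0.10 for adipocyte markers, a change of sign, -0.90 for blood cells, 0.75 for the cell cycle, 0.12 for endoplasmic reticulum stress, 0.11 for oxidative stress, -0.53 for pancreas, where Ctrb1 alone reached the filter, and -0.34 for stellate cells. A member was kept when its higher pool reached the filter. Dim members such as Top2a and Rrm2 thus entered only through the obese pool, which favours a larger cell cycle median.

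The original arrays alone gave 0.00 for bile acids, -0.20 for blood cells, 0.14 for the clock, 0.38 for female-biased genes, 0.09 for glucocorticoids, 0.01 for gluconeogenesis, 0.37 for glucose use, -0.80 for male-biased genes, 0.16 for oxidative stress, -0.11 for pancreas, 0.23 for the urea cycle and -0.03 for xenobiotics. The technical replicate arrays alone gave -0.04 for adipocytes, -0.12 for bile acids, -0.44 for blood cells, -0.06 for the clock, -0.25 for endothelium, 0.09 for female-biased genes, -0.19 for gluconeogenesis, 0.26 for glucose use, -0.07 for the leptin list, -1.26 for male-biased genes, 0.12 for oxidative stress and 0.27 for pancreas.

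Without each array in turn the medians ran from -0.40 to -0.27 for blood cells, -0.02 to 0.10 for the clock, -0.24 to -0.04 for endothelium, 0.24 to 0.33 for fatty acid oxidation, 0.11 to 0.37 for female-biased genes, -0.12 to 0.02 for gluconeogenesis and 0.26 to 0.37 for glucose use. They ran from -0.06 to 0.00 for the leptin list, -1.16 to -0.89 for male-biased genes, 0.11 to 0.19 for oxidative stress, -0.12 to 0.17 for pancreas, 0.09 to 0.18 for the urea cycle and -0.15 to -0.03 for xenobiotics. No paired analysis was possible because each phenotype was measured as 1 pool and no test was made. Signal over background is not known here, so differences of dim genes, such as those of the cell cycle, are uncertain in size.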

Other observations

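Outside the skeletal muscle list, placeholder symbols aside, the largest decreases in the obese pool were those of Pkia (15.4-fold), Fitm1 (13.2-fold), Itm2a (13-fold) and H19 (12-fold). Liver enzymes and secreted proteins were also among the lower genes, at smaller folds. Apart from Fitm1, the lower genes named here were chosen after their values were seen. Acnat2, an acyltransferase of fatty acid conjugation, was 6.61-fold lower (6.16 to 7.11), Upp2, a uridine phosphorylase, 7.37-fold (7.22 to 7.53), and Serpina7, the thyroxine-binding globulin, 6.02-fold (5.08 to 7.13). The methyltransferase Inmt was 8.10-fold lower (7.17 to 9.15), the oxidase Nox4 7.89-fold (7.30 to 8.53) and Gfra1, a receptor of a neurotrophic factor, 7.09-fold (6.23 to 8.07). Others outside the list are genes that muscle expresses, such as Fitm1, Cpt1b (7.72-fold), Aldoa (5.38-fold) and Pkm (5.83-fold). The 116 lower genes outside the list therefore still hold muscle genes, and how many was not counted. Among further higher genes, also chosen after their values were seen, the fructose transporter Slc2a5 was 3.28-fold higher (2.97 to 3.62), the drug exporter Abcb1b 3.54-fold (2.97 to 4.22), the signalling regulator Rgs16 3.52-fold (3.17 to 3.92) and the zinc transporter Slc39a4 2.75-fold (2.64 to 2.87). The obese levels of Pkia, Fitm1, Itm2a, Upp2, Serpina7, Inmt, Nox4, Gfra1 and Cpt1b and the lean level of Abcb1b lay below the level filter, so their folds have no firm size.

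All tests of the patterns that follow were chosen after the result was seen, except that the prediction for Cish was written before its own value was seen.

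Skeletal muscle transcripts were higher in the lean pool, and a candidate explanation is muscle tissue or RNA in that pool. It would bring transcripts of every muscle class, and 67.8% of the measured muscle genes were 2-fold higher in the lean pool: 14 of 14 fast fibre, 9 of 10 slow fibre, 21 of 24 energy, 29 of 41 sarcomere, 15 of 30 excitation and 11 of 27 regulation genes. Outside the 60 largest decreases it was 48.4% of 91 muscle genes against 1.07% of all genes, the lean levels of Acta1, Myl1 and Ckm were 13.10, 11.85 and 11.72, and 18 of the 146 muscle genes reached the level filter in the obese pool too. The values argue against heart muscle, as the heart-restricted genes had a median difference of 0.04 (smooth muscle genes -0.07), and against a fault of a single lean array, as the lean arrays differed by a median of 0.13 over the muscle genes. Expression of muscle genes by the liver cells of lean rats (median -2.45) cannot be told apart from muscle RNA, because only 1 lean pool was measured and the animals' own RNA was not analysed here.

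Male-biased liver genes were lower in the obese pool, with a median of -1.03. A smaller share of hepatocyte RNA would lower hepatocyte markers as well, but their median was 0.08 (0.03 to 0.11 over the array pairs), and likewise 0.08 (0.02 to 0.09) for the 5 markers below a level of 12, away from the top of the scale. Muscle RNA in the lean pool would act through Car3, without which the median was still -1.0 (-1.22 to -0.81). Weaker growth hormone signalling in the obese liver predicted a lower level of Cish, a gene induced by that hormone, and Cish stood at 7.66 in the lean and 5.80 in the obese pool, a difference of -1.86 (-2.11 to -1.61). Igf1, another target, had a difference of -0.03, and muscle also transcribes Cish and Socs2, so part of their excess in the lean pool may come from muscle RNA, and the hormone hypothesis stays open.

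Cell cycle genes were higher in the obese pool, with a median of 0.63, or 0.36 with an offset of 16 on the linear scale. A shift of all dim probe sets would move random lists of the same level too, but the middle 95% of their medians reached only 0.12. A fault of a single array would leave some pair of arrays without the difference, but the lowest of the 4 pairs gave 0.53 and the highest 0.81. More leukocytes in the obese liver would raise their markers, but macrophage markers had a median of -0.25 and lymphocyte markers one of -0.21. The lymphocyte markers were dim, with 3 of 13 at the level filter in the obese pool. Whether other tissue in the lean pool carried leukocyte markers was not tested, so these medians do not exclude more leukocytes in the obese liver. Proliferation of hepatocytes or other liver cells was not tested and stays a hypothesis, as does a difference carried by 1 of the 4 animals in a pool.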
